A study of Mus musculus with 8 samples.

How the data were processed

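Methylated DNA was measured by mDIP, an immunoprecipitation of denatured, sonicated genomic DNA with an antibody against 5-methylcytidine. Per the labels' protocols, DNA set aside before the precipitation (input) was labelled with Cy3 and the antibody-bound DNA of the same sample with Cy5, and both were hybridised to 1 Agilent CpG island array of the mouse. The 8 samples are 8 groups of 1 array each. They are wild-type embryonic stem (ES) cells, aid-/- ES cells, ES cells without Mbd4 (a thymine glycosylase that binds methylated CpG), ES cells with a knockdown of Gadd45a (a DNA damage response gene), and liver and spleen of aid-/- and of mbd4-/- mice aged 6 months. No wild-type liver or spleen was analysed here. Dyes were the same way round on every array, so dye bias cannot be separated from enrichment, and whether it was equal between arrays was not tested.

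The deposited scanner files hold spot intensity values, per the file headers written by Agilent Feature Extraction, version 10.7.3.1 for the ES mbd4-/- and Gadd45a knockdown arrays and 10.9.1.1 for the other 6. The processed signals in them are background-subtracted and dye-normalised with 1 linear factor per channel, per the file headers, and the older version states spatial detrending. The deposited files also hold the scanner's log10 ratio of Cy5 over Cy3, which was used only to check the direction of the processed signals. The deposited value table of the series is a score with a mean of 0 and an SD near 1 on each array. Its medians ran from −0.21 to −0.03, it held 54869 to 78421 values per array, and it correlated with the scanner log ratio of the same array over probes at r = 0.898 to 0.972, which gives its direction and its centring. Its log base and scale stay unknown, so it was multiplied by 1.204, the mean SD of the scanner log2 ratios, and used only as an alternative. Positions are in genome build mm9, per the file headers. What the authors did between the scanner and the value table is not given in the sources used here.

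The array has 94687 spots, of which 5950 are controls. Of the 88737 probes of 45 to 60 nucleotides, 326 without a position, 132 marked as outliers and 7309 whose input signal was not well above background on some array were left out, and 81105 were used. For each probe the log2 ratio of bound over input was taken from the processed signals and each array was centred on its median, with no loess or quantile step, because most probes of such an array carry signal and many regions can shift one way. Probes no more than 500 bp apart were joined into regions, and the value of a region is the mean of its probes. Regions with at least 3 probes were kept, 13147 of 15415, with a median of 5 probes and a median length of 622 bp. Gene names are those of the array design: 12512 regions carry one, 9484 of the 10545 names are current symbols and 1001 more are older synonyms in a RefSeq gene table (assembly GRCm38, used for names alone). A region takes the name that most of its probes carry in the design, and no annotation of exons or introns was used here. A log ratio shows how strongly a region was bound by the antibody relative to the other regions on the same array, and is no methylation percentage.

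The number of arrays limits the precision, and signal over background differs between them. The share of probes whose bound signal was well above background was 65.5% for ES aid-/-, 91.1% for ES wild type, 81.1% for ES mbd4-/-, 84.5% for the Gadd45a knockdown, 83.3% and 92.3% for aid-/- and mbd4-/- liver, and 81.9% and 90.6% for aid-/- and mbd4-/- spleen. The highest log ratios also differed. The 98th percentile of autosomal regions, called the plateau here, was 4.34, 3.36, 4.31 and 2.80 in ES aid-/-, wild type, mbd4-/- and Gadd45a knockdown, 2.23 and 4.02 in aid-/- and mbd4-/- liver, and 2.24 and 3.66 in aid-/- and mbd4-/- spleen. The log ratio also followed probe GC differently: probes under 40% GC had a median of 1.19 on the ES aid-/- array and −1.48 on the Gadd45a knockdown array. Arrays correlated over probes at r = 0.322 (Gadd45a knockdown and aid-/- liver) to 0.856 (mbd4-/- liver and mbd4-/- spleen).

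Because each group is 1 array, comparisons of 2 arrays have no test. A region was listed as higher or lower when its values differed by at least 1 on the log2 scale and at least 75% of its probes differed in that direction. A region with no bound probe above background on the dimmer array has only a bound there, which sets the brighter value against the array's lowest signal above background. On simulated unchanged pairs with the observed probe noise (SD 0.728), 3.28% of the unshifted regions (425) passed this rule in either direction, and it recovered 83% of regions shifted by 1.5 log2 and all of those shifted by 3 log2. ES cells were compared with liver and spleen, and liver with spleen, by limma over all 8 arrays, with arrays of different genotype standing in as replicates of a tissue. The genotypes aid-/- and mbd4-/- were compared by limma over 6 arrays with tissue as a block. Tests used lmFit and eBayes with Benjamini-Hochberg adjustment at 0.05. On simulated data the first fit recovered 81% of regions shifted by 2 log2 and 97% of those shifted by 4 log2, and the genotype fit 37% and 87%. P-values measure only the spread between these arrays.

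The 10 gene lists were fixed before the data were examined: pluripotency, germline, imprinted, developmental regulators bound by Polycomb, housekeeping, protocadherin, liver, blood and immune, fibroblast, and methylation machinery genes. For comparisons of 2 arrays, the median of a list was placed among 10000 random lists of as many regions with a like mean level, as a description of those arrays. For limma contrasts lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The rule for named regions, also fixed beforehand, takes the 10 gene-named regions with the largest difference in each direction among those that pass, the 2 members of each list with the largest difference in each direction, and Mbd4 and Gadd45a on every array. A name counts under each part of the rule that takes it.

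Alternatives fixed beforehand were centring on the mode of the low log ratios, scaling to an equal spread, normexp background correction with an offset of 50, quantile normalisation for the limma fits between tissues, the deposited values, a minimum of 5 probes, no probe filter, the median of probes, autosomes only, other blocks, and leaving out each array. Normexp used the median spot signals, because the mean signal is in only 2 of the 8 files. Chosen after seeing the data were a correction for GC in bins of 2%, scaling to a common plateau, both together, a correction by chromosome, the scan day and slide, and quantile normalisation for the fit between genotypes. The arrays lie on 6 slides and were scanned on 4 days. Scan day 1 holds ES aid-/-, ES wild type, aid-/- liver and aid-/- spleen, day 2 both mbd4-/- tissues, day 3 ES mbd4-/- and day 4 the Gadd45a knockdown. ES mbd4-/- and the Gadd45a knockdown cannot be told apart from their scan days when set against wild type, nor can aid-/- from mbd4-/- in liver and spleen. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8).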

Results

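The series set out to examine a demethylation pathway specific to CpG islands in mouse ES cells, and measured antibody-bound over input DNA on 8 arrays. ES cells gave 4 arrays (wild type, aid-/-, mbd4-/- and Gadd45a knockdown), and liver and spleen gave 2 each (aid-/- and mbd4-/-). No group has a replicate array, so a difference between 2 arrays compares those arrays, and its only measured error is the spread over the probes of a region. Values are region means of log2 bound over input, relative to the median of their array, given with the SD over probes where it is printed. The median background-subtracted input signal ran from 87.6 (aid-/- liver) to 235 (Gadd45a knockdown), and the bound signal from 31.5 (ES mbd4-/-) to 100 (mbd4-/- spleen).

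Mbd4 and Gadd45a, named in the labels, came first. Mbd4 had 2 probes (chromosome 6, 115803273 to 115803411), with means of −0.42 in ES mbd4-/-, 0.46 in ES wild type, 0.97 in mbd4-/- liver and 0.93 in mbd4-/- spleen. The Gadd45a region (chromosome 6, 66986497 to 66987387, 7 probes) stood at −0.54 in the knockdown and −0.65 in wild type. These probes report antibody binding, and the input signal was not used to find a deletion, so they check neither a deletion nor a knockdown.

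The first question was whether CpG islands gain methylation in aid-/- ES cells. The largest differences with aid-/- above wild type lay at imprinted regions, which carry methylation on 1 parental allele. Whether aid-/- gained or wild type lost methylation there cannot be told from these 2 arrays. Zrsr1, an imprinted relative of a splicing factor gene, stood at 3.75 ± 0.39 (SD over 9 probes) in aid-/- and −2.04 ± 1.39 in wild type, a difference of 5.79 (chromosome 11, 22872000 to 22873052). Peg3, a zinc finger gene expressed from the paternal allele, differed by 5.05 (4.19 against −0.86, chromosome 7, 6682111 to 6683212). Airn, the non-coding RNA that silences Igf2r on the paternal chromosome, differed by 4.82 (3.79 against −1.04, chromosome 17, 12934260 to 12935460). Kcnq1ot1, a non-coding RNA that silences its imprinted cluster, differed by 4.65 (4.11 against −0.54, chromosome 7, 150481208 to 150482535).

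All 10 gene-named regions with the largest excess in aid-/- belonged to imprinted genes. Besides those, they were Impact (4.83), Grb10, a growth-inhibiting adaptor (4.70), Peg10 (4.43), Gnas, which encodes a G protein subunit (4.34), Plagl1 (4.22) and Nnat (3.91). Of the 33 regions of the imprinted list, 20 were higher in aid-/- and 1 was lower, with a median difference of 1.62 that lay above all 10000 random lists (0.81 with GC correction at one plateau, also above all). In the germline list, genes of meiosis and of the piRNA pathway, 12 of 21 regions were higher and none lower, among them Tex11 (1.86) and Piwil2 (1.85). Its median difference of 1.13 lay at the 94.1th percentile of random lists of a like level, whose median was 0.91, and became −0.22 in the deposited values. In the pluripotency list 6 of 21 regions were higher, with Esrrb at 2.31, and none was lower. One of them, Sox2, had no bound probe above background on either array. The protocadherin list had 4 of 13 regions higher, such as Pcdha12 (1.77) and Pcdha6 (1.51), and 1 lower, Pcdhgb8 (−1.42). Its median, 0.71, lay at the 68.3th percentile and became −0.23 in the deposited values.

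Developmental regulators bound by Polycomb were mostly even: of 243 regions 14 were higher, led by Hoxc4 (1.91) and the limb and heart regulator Tbx5 (1.66), and 4 were lower, led by Irx3 (−1.77) and the B cell regulator Pax5 (−1.22). Of 44 housekeeping regions, ubiquitin gene Ubb was higher (1.05) and 2 were lower, Mcm5 of the replication helicase among them, which had no bound probe above background in aid-/- and was at least 1.21-fold lower (measured −1.76). In the methylation machinery list 2 of 25 were higher, Mbd3 (1.74) and Gadd45b (1.55). Higher regions numbered 2 of 14 in the blood and immune list (Cd37, 1.08) and 2 of 18 in the fibroblast list (Col6a2, 1.09, and Loxl1, 1.05), with none lower in either, and neither of the 2 liver regions passed. The gene-named regions with the largest deficit in aid-/- were Cbx7, a Polycomb protein (−3.05), March8 (−2.32), the Notch target Hes1 (−2.23), Hibadh (−2.22), Mir1190 (−2.21), Pde4dip (−2.17), Vps4b (−2.16) and Dhx15 (−2.13). Rdbp and Ntf5 had no bound probe above background in aid-/- and were at least 2.06-fold and 1.08-fold lower, against measured values of −2.32 and −2.13. In aid-/-, 1 of 3 bound probes was above background at Cbx7 (SD over probes 2.47), Hes1, Mir1190 and Pde4dip. At March8, Hibadh and Vps4b it was 2 of 3, and at Dhx15 3 of 6. Wild-type values of Cbx7, Hes1, Mir1190 and Pde4dip were 0.62, 0.02, 0.20 and −0.18, under the wild-type plateau of 3.36. These deficits thus rest on few probes above background, at regions low in wild type as well. With normexp background 5 regions were lower.

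Over all regions, 895 were higher and 481 lower in aid-/- than in wild type (65.0% higher). With each array centred on its low mode, 1205 were higher and 255 lower (82.5%), and with arrays scaled to one plateau, a setting chosen after seeing the data, 348 and 211. With normexp background 245 were higher and 5 lower. Of the list members named above, Tex11, Tbx5, Mcm5, Pcdha6, Cd37, Col6a2 and Loxl1 no longer passed at one plateau. A bound alone stood behind 11 of the 1376 differences. Both arrays were scanned on day 1, so this comparison lies within 1 scan day, but they lie on different slides. Over probes, ES aid-/- correlated more with aid-/- liver (r = 0.753) and aid-/- spleen (0.740) than with ES wild type (0.645). Probes under 40% GC had medians of 1.19, 0.33 and 0.54 on the aid-/- arrays of ES cells, liver and spleen, and negative medians on all others. A technical trait shared by the aid-/- arrays thus cannot be told apart from genotype here.

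Imprinted regions also led the comparison of ES cells without MBD4, a glycosylase that removes thymine from T:G mismatches. Zrsr1 differed from wild type by 6.21 (4.17 ± 0.34 against −2.04 ± 1.39), Mcts2 by 5.60 (4.56 against −1.04), Plagl1, a zinc finger gene, by 5.45 (5.33 against −0.12) and Nap1l5 by 5.38 (5.12 against −0.26). Peg3 (5.17), Airn (5.16), Nnat (4.88), Peg10 (4.84), Grb10 (4.82) and Kcnq1ot1 (4.82) completed the 10 largest, from which Impact and Gnas were missing. The Gnas region named for aid-/- still passed in mbd4-/-, at 4.44 against −0.35, whereas Impact did not pass, at 0.53 against −0.71. Of the 33 imprinted regions 18 were higher and none lower, with a median difference of 1.24 above all 10000 random lists (0.91 with GC correction at one plateau, also above all).

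Those 18 regions, of 15 genes, were higher in both aid-/- and mbd4-/-. Their median was 4.00 in ES aid-/-, 4.35 in ES mbd4-/- and −0.19 in both wild type and the Gadd45a knockdown. Liver and spleen stood between, at 1.65 and 3.35 in aid-/- and mbd4-/- liver and 1.50 and 2.84 in aid-/- and mbd4-/- spleen, on arrays with different plateaus. Wild type and the knockdown thus lay below every liver and spleen array in the median. A loss in the wild-type line would give the same differences as a gain in the mutants. Peg13 (3.76) and Dlk1 (2.54) were the regions with the highest values in wild type.

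**Figure D1:**
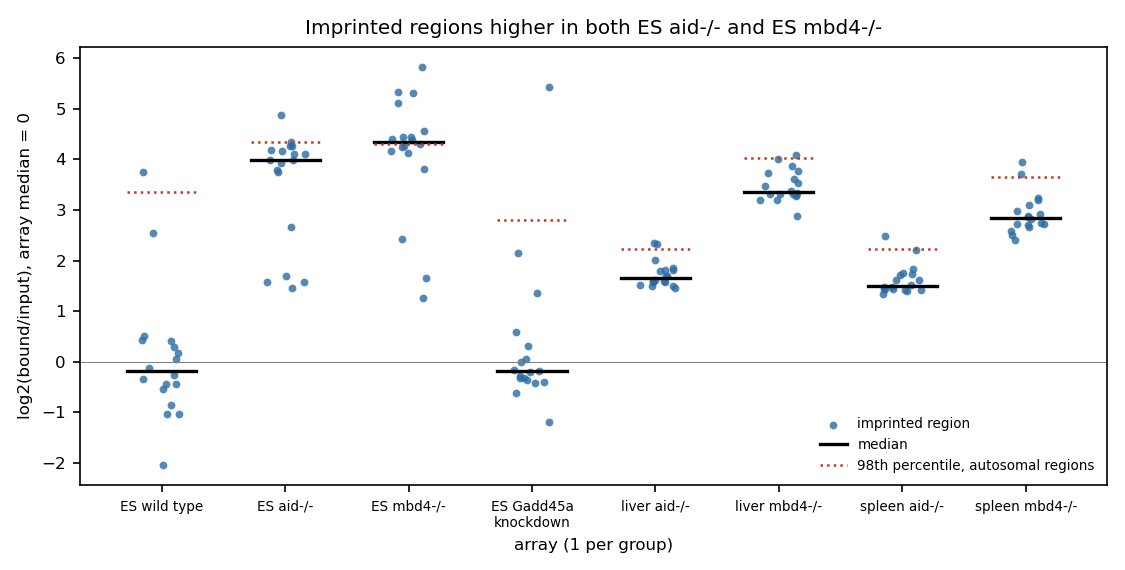
Log2 bound over input of the 18 imprinted regions that were higher in both ES aid-/- and ES mbd4-/- than in ES wild type, on each of the 8 arrays (1 point per region, bar at the median, dotted line at the 98th percentile of the array's autosomal regions). Medians are 4.00 and 4.35 in ES aid-/- and mbd4-/- and −0.19 in ES wild type and Gadd45a knockdown.

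In other lists of the mbd4-/- comparison, 10 of 21 germline regions were higher, such as Tdrd1 (1.78) and Piwil2 (1.47) of the piRNA pathway, and none was lower. The germline median was 1.00, at the 74.6th percentile of random lists, and 0.14 with GC correction at one plateau, at the 52.3th. Of 21 pluripotency regions 6 were higher, with Esrrb (2.06) in front and Sox2 at least 2.16-fold higher (measured 1.45, with no bound probe above background in wild type). Of 13 protocadherin regions 6 were higher, such as Pcdha6 (1.97) and Pcdha10 (1.88), and Pcdhgb8 was lower (−2.15). Of 243 Polycomb regions 13 were higher, such as Neurod1 (2.08) and Hoxd12 (1.56), and 3 lower, such as Irx3 (−1.29) and Dlx5 (−1.21). Single regions were higher in the housekeeping (Rpl7, 1.11), liver (F2, which encodes prothrombin, 1.08, and 0.09 at one plateau), blood and immune (Zap70, 1.18) and fibroblast lists (Loxl1, 1.02). Of 25 methylation machinery regions Mbd3 was higher (1.29) and the region shared by Ift122 and Mbd4 lower (−1.07). The regions with the largest deficit in mbd4-/- were Samd12 at −1.12 against 3.50 (−4.62, chromosome 15, 53733924 to 53734249), Acss2, an acetyl-CoA synthetase, at −3.36, and Wdr67 at −2.76. Arhgef19 (−2.31), Atpbd4 (−2.27), Cs, the citrate synthase gene (−2.22), Fndc3b (−2.19), Pcdhgb8 and Maff (−1.96) followed, and 4932441J04Rik was at least 1.59-fold lower (measured −1.99). In total 1044 regions were higher and 316 lower (76.8% higher). Scaled to one plateau, 384 were higher and 129 lower, and with normexp background 160 and 15 (91.4%). Of the list members named here, Tdrd1, Piwil2, Hoxd12, Rpl7, F2, Zap70, Loxl1, Mbd3 and Ift122 no longer passed at one plateau.

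Of the regions higher in aid-/- and in mbd4-/-, 562 were shared. Lists independent of each other would share 71.1, and unchanged arrays set against the same wild-type array shared 41.1 on average over 100 simulated draws. Lower regions shared 84, against 11.6 and 40.8. Differences correlated over regions at r = 0.671 (0.419 simulated), with a covariance of 0.280 (0.0762 simulated), and regions are not independent replicates. Part of the excess may come from the 1 shared wild-type array. Part may come from the range, since the plateaus were 4.34 and 4.31 in aid-/- and mbd4-/- against 3.36 in wild type. At one plateau the higher regions fell to 348 and 384, and the overlap in that setting was not counted. The simulated draws hold probe noise alone and were counted without the rule on 75% of probes. Of the 562, 415 (73.8%) lay at or above 50% of the plateau in all 4 liver and spleen arrays, against 7.56% of all regions. Their median was 1.55 in wild type, 3.29 in aid-/- and 3.14 in mbd4-/-, and 46.6% reached that level in wild type too. The median of all regions in wild type was −0.11, and no regions of a like level were compared. An excess over all regions thus follows at least in part from how the 562 were chosen. Of the 481 regions lower in aid-/-, 0.832% lay at or above 50% of the plateau in wild type.

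In the Gadd45a knockdown the named regions with the largest differences from wild type lay outside the imprinted list. Nefm, which encodes a neurofilament subunit, stood at 3.73 ± 0.33 (SD over 14 probes) against −0.34 ± 1.17, a difference of 4.07 (chromosome 14, 68741625 to 68743210). Lower regions went further: Ston2, an endocytic adaptor gene, was at −1.57 against 3.79 (−5.36, chromosome 12, 92885819 to 92886620), and the signalling ligand gene Wnt3a at −0.33 against 3.79 (−4.12). Among protocadherin genes Pcdhga11 was lower at −4.19, Pcdhgb8 at −4.18 and Pcdhga12 at −4.18. Fam46b (−4.04), Samd12 (−3.93) and the ephrin receptor gene Epha2 (−3.79) were also among the largest deficits.

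Of 21 germline regions 6 were lower in the knockdown, such as Taf7l (−1.43) and Mael (−1.38), and none was higher (Taf7l no longer passed at one plateau), with a median of −0.82 at the 2.07th percentile of random lists. Of 13 protocadherin regions 4 were lower and Pcdha12 was higher (1.42). In the Polycomb list 19 of 243 regions were lower, such as Irx3 (−2.44), and 7 higher, such as Tbx2 (1.78) and Meis1 (1.63). Its median of −0.09 lay below all 10000 random lists, as it did with GC correction (−0.03) and with GC correction at one plateau (−0.07). It became 0.36 with arrays centred on the low mode and 0.002 at an equal spread. The median of all regions was 0.62 and 0.18 in those settings, and the list was not placed among random lists there. Imprinted regions were mostly even, with 3 of 33 higher, such as Peg13 (1.68) and Slc38a4 (1.30), and 1 lower, Trappc9 (−1.72). The pluripotency list had 2 of 21 lower, one of them Sall4 (−0.04 against 3.63, a difference of −3.67). The methylation machinery list had 2 of 25 lower, Mbd3 (−3.67) and the dioxygenase gene Tet3 (−1.66). Single regions passed in the housekeeping (Psma3, a proteasome subunit, 2.75), fibroblast (Pdgfra, 1.01), liver (F2, −1.94) and blood and immune lists (Zap70, −1.22). Further regions among the 10 furthest above wild type were Vezf1 (2.85), the histone variant gene H2afy (2.75), Sec22a (2.66), 4930526I15Rik (2.65), Kifc5b (2.65), Zfp53 (2.57), the lactate dehydrogenase gene Ldha (2.51) and Slitrk3 (2.49). SDs over probes reached 2.75 in these (H2afy, 3 probes).

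Counts for the knockdown were 994 higher and 773 lower (56.3% higher), and the split depended on the scale: 3194 and 405 (88.8%) when centred on the low mode, 622 and 966 (39.2%) at an equal spread, 631 and 932 (40.4%) in the deposited values, and 138 and 771 (15.2%) with normexp background. Centring on the low mode moved the median of all regions from 0.18 to 0.62. With aid-/- the knockdown shared 47 higher and 10 lower regions (67.7 and 28.3 for independent lists, 53.8 and 53.4 simulated), at r = −0.197 (0.320 simulated) and a covariance of −0.0945 (0.0760 simulated). With mbd4-/- it shared 92 and 32 (78.9 and 18.6 independent, 41.0 and 40.5 simulated), at r = −0.0156 (0.386 simulated) and a covariance of −0.00731 (0.0763 simulated).

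Regions lower in wild type than in all 3 other ES arrays numbered 25, and 6 were higher. With the other arrays in the place of wild type, 76 regions were lower than the rest for aid-/-, 19 for mbd4-/- and 642 for the Gadd45a knockdown.

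**Figure D2:**
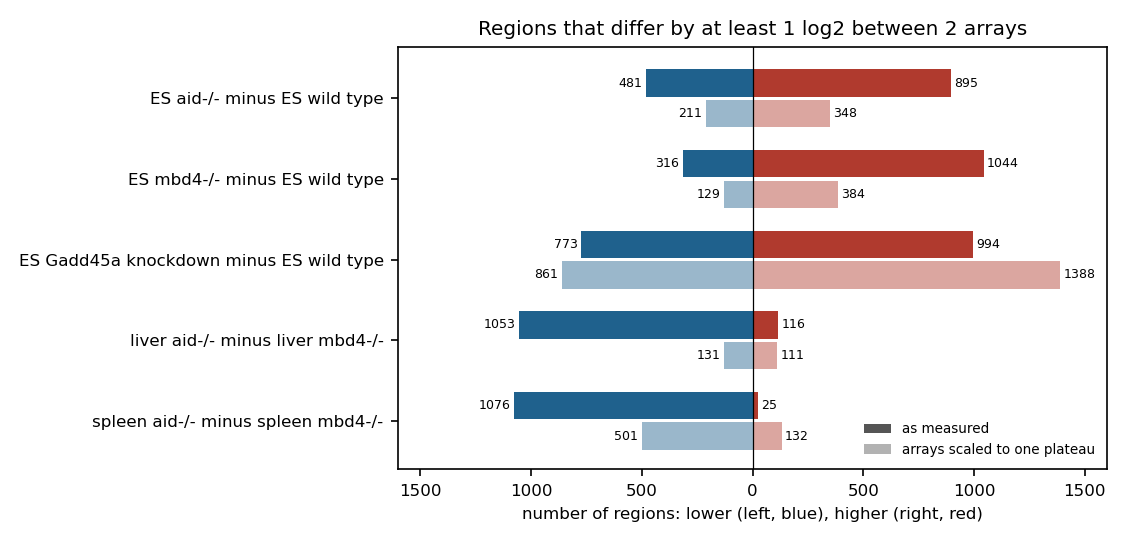
Numbers of regions higher (right, red) and lower (left, blue) by at least 1 on the log2 scale in 5 comparisons of 2 arrays, as measured (dark) and with arrays scaled to one plateau (light). In liver 1053 regions are lower in aid-/- as measured and 131 after scaling.

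In liver and spleen the labels hold no wild type, so aid-/- was set against mbd4-/-. In aid-/- liver, Dst, a cytoskeletal linker gene, was lower by the most (1.37 ± 2.03 against 4.80 ± 0.25, −3.43, chromosome 1, 34234710 to 34234946), followed by the plexin gene Plxnb2 (−2.69), Ltbp3 (−2.64), Trappc9 (−2.64), Fam108a (−2.59), Trrap (−2.53), Zbtb7a (−2.52), Git2 (−2.52), Spred2 (−2.52) and AW555464 (−2.48). Higher regions were Pax6os1 (1.98), Phf10 (1.92), Hist1h2bk (1.69), the GATA cofactor gene Zfpm1 (1.55), Thg1l (1.55), the potassium channel gene Kcnj3 (1.53), Rpl31 (1.44), Pcdh17 (1.43), Gm2058 (1.43) and Ciz1 (1.40). None of the 3 Hist1h2bk probes was above background in the bound channel of aid-/- liver. At one plateau Plxnb2 (−0.96), Ltbp3 (−0.77), Trappc9 (−0.72), Trrap (−0.90), Zbtb7a (−0.87), Git2 (−0.71), Spred2 (−0.54) and AW555464 (−0.75) no longer passed. Imprinted regions were lower in 22 of 33 cases, with Trappc9 and Peg13 (−2.28) at the front and a median of −1.67 below all random lists. After scaling to one plateau and GC correction this median was −0.30.

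Germline regions were lower in 17 of 21 cases in aid-/- liver, such as Tuba3a (−2.29) and Dpep3 (−2.15), but their median of −1.40 became 0.33 with arrays scaled to one plateau. Likewise 7 of 13 protocadherin regions were lower, such as Pcdha2 (−1.55) and Pcdha4 (−1.48), and their median of −1.03 became 0.23. Random lists of a like level had medians of −1.625 and −1.25, which put the germline and protocadherin lists at the 98.9th and 82.8th percentiles. Neither list was thus lower than regions of a like level. Lower regions numbered 6 of 21 for pluripotency (Sall4, −1.94, and Tbx3, −1.33), 2 of 18 for fibroblast (Col6a2, −1.88), 1 of 14 for blood and immune (Cd37, −1.30) and 1 of 2 for liver genes (F2, −1.66), with none higher. Among 243 Polycomb regions 10 were higher, such as Hoxc4 (1.25) and Pax3 (1.19), and 8 lower, such as Wnt3a (−1.96) and Gata6 (−1.52). No housekeeping region passed, and in the methylation machinery list the uracil glycosylase gene Smug1 was higher (1.00) while Mbd3 (−2.16) and Tet3 (−1.33) were lower. None of the list members named in liver passed at one plateau, where the differences of Sall4 (0.02), Tbx3 (0.31), Pcdha2 (0.17), Pcdha4 (0.29) and Tet3 (0.25) turned positive. In total 116 regions were higher and 1053 lower (9.92% higher). Scaling moved that share most: 111 and 131 at one plateau (45.9%), 297 and 346 at an equal spread (46.2%), 176 and 184 in the deposited values (48.9%) and 395 and 883 centred on the low mode (30.9%).

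In spleen the X chromosome led. The 10 gene-named regions with the largest deficit in aid-/- all lay on it: Htatsf1 (−0.97 ± 0.44 against 3.08 ± 0.37, −4.05, 54306421 to 54307262), Mir505 (−3.96), the nucleotide carrier gene Slc25a5 (−3.95), Tbl1x (−3.77), Ddx26b (−3.74), Otud5 (−3.66), the cohesin gene Smc1a (−3.62), the ubiquitin ligase gene Huwe1 (−3.56), 2900002K06Rik (−3.42) and Fam120c (−3.33). Of 353 X regions 311 were lower in aid-/- and none higher. The median X region stood at 2.28 in mbd4-/- spleen, 0.18 in aid-/- spleen, 0.32 in mbd4-/- liver and 0.14 in aid-/- liver. Input signal of chromosome X was 0.65 above the median array in mbd4-/- spleen.

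**Figure D3:**
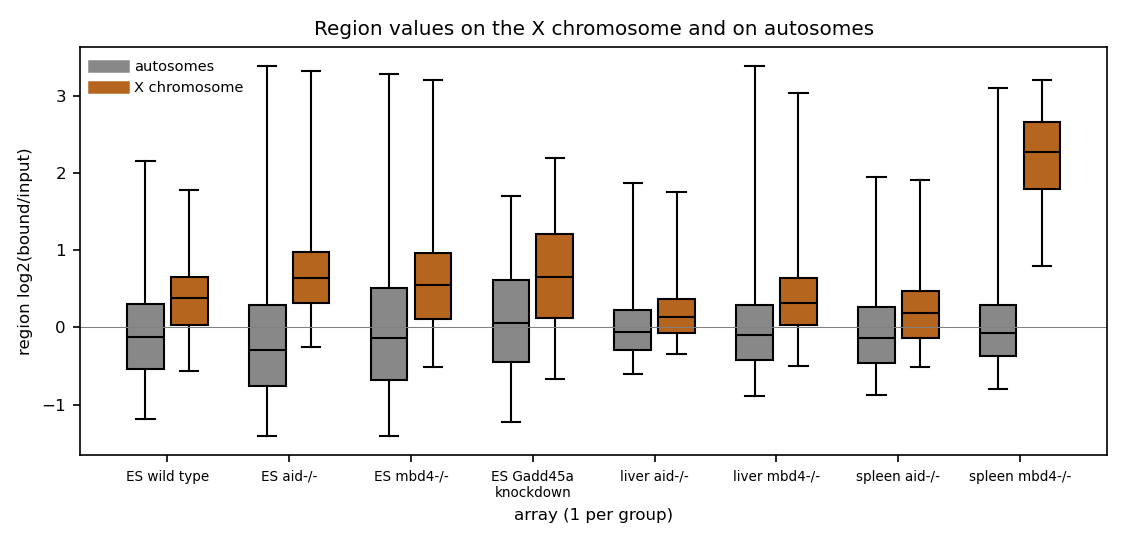
Region values of log2 bound over input on autosomes (grey) and the X chromosome (orange) on each of the 8 arrays (line at the median, box over the middle 50% of regions, whiskers from the 5th to the 95th percentile). The X median is 2.28 in mbd4-/- spleen and at most 0.66 elsewhere.

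Of 33 imprinted regions 20 were lower in aid-/-, such as Trappc9 (−1.82), with a median of −1.19 (−0.36 with GC correction at one plateau). Of 21 germline regions 15 were lower, such as Tuba3a (−2.02) and Sycp2 (−1.76), and 4 of 13 protocadherin regions, such as Pcdha4 (−1.25). The medians of these lists were −1.33 and −0.79, and became 0.12 and 0.49 at one plateau. Random lists of a like level had medians of −1.31 and −1.05, which put these lists at the 39.7th and 90.3th percentiles. Of 14 blood and immune regions 4 were lower, such as Sfpi1, the myeloid regulator PU.1 (−1.71), and Zap70, a T cell kinase (−1.27). Lower regions also numbered 2 of 21 for pluripotency (Sall4, −1.37, and Esrrb, −1.16), 2 of 18 for fibroblast (Col6a2, −1.24), 1 of 2 for liver (F2, −1.31) and 3 of 25 for methylation machinery (Mbd3, −2.34). Of 243 Polycomb regions 3 were higher and 8 lower, X-linked Sox3 (−2.32) and Hoxa3 (−2.14) among the latter. No housekeeping region passed. At one plateau the differences of Sall4 (0.08) and Pcdha4 (0.21) turned positive in spleen, and Esrrb, Tuba3a, Sycp2, Trappc9, Hoxa3, F2, Sfpi1, Zap70 and Col6a2 no longer passed. Among the regions higher in aid-/- were Evx2 (1.38), Sall1 (1.35), Foxb1 (1.33), Fam5b (1.33), Foxf1a (1.29), the neuropeptide gene Tac1 (1.27) and Grik2 (1.19), while Hist1h2bk had no bound probe above background on either array and 8430427H17Rik none in aid-/-. In total 25 regions were higher and 1076 lower (2.27% higher), against 132 and 501 (20.9%) at one plateau. Other settings kept the excess: 80 and 1243 at an equal spread, 40 and 536 in the deposited values, 0 and 1210 with normexp, and 22 and 1120 centred on the low mode.

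ES cells were next set against liver and spleen. Rbfox3, which encodes the neuronal protein NeuN, was higher in ES cells by 3.08 (SE 0.283, limma adjusted p = 0.0139; 3.37 ± 0.54 in ES cells and 0.29 ± 0.16 in tissues, SD, n = 4 each; chromosome 11, 118768579 to 118769061). Atf7ip, a partner of the SETDB1 histone methyltransferase, was higher by 3.43 (SE 0.278, limma adjusted p = 0.0106; 3.43 ± 0.54 against −0.01 ± 0.04, n = 4 each; chromosome 6, 136467067 to 136467757). Hoxa3, a patterning gene, was lower by the most (−3.76, SE 0.442, limma adjusted p = 0.0213; −2.29 ± 0.65 against 1.47 ± 1.44, n = 4 each). Stx1a, a synaptic vesicle fusion gene, was lower at −2.82 (SE 0.279, limma adjusted p = 0.0139; −0.24 ± 0.21 against 2.58 ± 0.50, n = 4 each), and the transcription factor gene Nfix at −2.48 (SE 0.268, limma adjusted p = 0.0162, n = 4 each).

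In all, 11 regions were higher and 18 lower in ES cells, at limma adjusted p-values of 0.0106 to 0.0427, and 1988 of 13147 had an unadjusted p under 0.05. The other named regions higher in ES cells were 3110007F17Rik on the X chromosome (3.72), Slitrk1 (2.65), D130017N08Rik (2.62), Mfap2 (2.54), the MHC gene H2-Eb1 (2.52), Mir10a (2.33), Slc7a14 (1.95) and the ion channel gene Accn1 (1.47). Lower were Msl3l2 (−3.28), Agap2 (−2.95), BC057022 (−2.92), Ehbp1l1 (−2.89), A930004D18Rik (−2.64), Aff3 (−2.42) and Sall1 (−2.34). The calls for H2-Eb1, Mir10a and Ehbp1l1 ended with GC correction, at differences of 2.65, 2.58 and −2.68, alone or with centred chromosomes, but not with GC correction at one plateau. Between settings the split moved to 24 higher and 100 lower centred on the low mode, 49 and 423 at an equal spread, 88 and 294 after quantile normalisation, 34 and 328 in the deposited values, and 69 and 357 at one plateau. With genotype as a block on the 6 aid-/- and mbd4-/- arrays 785 were higher and 746 lower, on 2 residual degrees of freedom. With scan day as a block 5 were higher and none lower, and within scan day 1 alone 162 and 20, on 1 residual degree of freedom. Without the mbd4-/- liver array no region passed. The counts higher and lower were 1 and 0 without ES aid-/-, 3 and 0 without ES wild type, 1 and 0 without ES mbd4-/-, 123 and 74 without the Gadd45a knockdown, 7 and 33 without aid-/- liver, 5 and 20 without aid-/- spleen, and 4 and 4 without mbd4-/- spleen.

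Among the lists, 2 Polycomb regions passed over all regions, both lower in ES cells, Hoxa3 and Gata3, a lymphoid regulator (−2.29, limma adjusted p = 0.0399). Adjusted over the list alone, 6 Polycomb regions were higher and 8 lower. The largest differences upward were Irx5 (2.72, limma adjusted p = 0.0892) and Nkx2-5 (2.20, limma adjusted p = 0.0744). The median of this list was −0.01 and its mean 0.01, so they differed in sign. The pluripotency list was lower (median −0.26, camera adjusted p = 0.0325), with Tbx3 at −2.36 (limma adjusted p = 0.0537) and Nr5a2 at −1.27, and 3 regions lower adjusted over the list alone. Its camera adjusted p was 0.224 with an estimated correlation. The housekeeping list was lower as well (median −0.27, camera adjusted p = 0.0325, and 0.674 with an estimated correlation), but its median was 0.02 at an equal spread and 0.08 after quantile normalisation. The 2 liver regions, Foxa3 (1.18) and F2 (0.94), were higher as a list (camera adjusted p = 0.0325, and 0.224 with an estimated correlation), with 1 region adjusted over the list alone. Of protocadherin regions 2 were lower adjusted over the list alone, with Pcdha12 at −2.30, and the camera adjusted p was 0.0693. The imprinted, germline, blood and immune, fibroblast and methylation machinery lists had no region past the test either way and camera adjusted p-values of 0.716, 0.137, 0.479, 0.826 and 0.233.

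Between liver and spleen limma found 0 regions, and 184 had an unadjusted p under 0.05, with 2 arrays per tissue. Differences for the developmental regulators Sox9 (1.70) and Tbx3 (1.66) were the largest upward in liver in the Polycomb and pluripotency lists, each at a limma adjusted p of 1.00. The Polycomb list was lower in liver (median −0.05) and the housekeeping list higher (0.12), each at a camera adjusted p of 0.0371 and at 0.957 with an estimated correlation. At an equal spread 30 regions passed and in the deposited values 7.

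Between aid-/- and mbd4-/- over ES cells, liver and spleen, limma found 0 regions with tissue as a block, and 1676 had an unadjusted p under 0.05. The smallest limma adjusted p was 0.386. Imprinted regions were lower in aid-/- as a list (median −0.95, camera adjusted p = 2.07e-06, and 0.611 with an estimated correlation), with Mcts2 and Nap1l5 at −2.10 each and 17 of 33 regions lower adjusted over the list alone. By tissue, the imprinted median was −0.11 in ES cells, −1.67 in liver and −1.19 in spleen. With GC correction at one plateau these medians were −0.16, −0.30 and −0.36. The germline list was lower too (median −0.78, camera adjusted p = 7.44e-05, and 0.611 with an estimated correlation), with Tuba3a at −1.64, but its median was 0.10 after quantile normalisation and 0.20 at one plateau. The Polycomb list was higher (median 0.10, camera adjusted p = 3.19e-08, and 0.611 with an estimated correlation), with Evx2 at 1.02 and Pax6 at 1.00. After GC correction Evx2 stood at 0.56 and Pax6 at −0.17. Leaving out either ES array gave the same fit, since the remaining ES array is taken up by its tissue block. That fit, of liver and spleen alone, called 64 regions higher and 1087 lower, on 1 residual degree of freedom. Its aid-/- and mbd4-/- arrays also differ in scan day and plateau.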

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

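The tests of explanations in this part, and the test of a difference between tissues, were chosen after the results were seen.

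For the difference between aid-/- and mbd4-/- in ES cells against that in liver and spleen, limma's interaction term passed for 490 regions, 431 of them with a higher difference in ES cells and 59 with a lower one, at a smallest adjusted p of 0.000573. This test leaves 1 residual degree of freedom, which comes from liver against spleen alone. The ES difference rests on 1 array per genotype and has no spread of its own, which is assumed to equal that of the tissues. After GC correction 445 regions passed, after scaling to one plateau 11, and after both 15. At one plateau, with or without GC correction, lower differences in ES cells outnumbered higher ones, so the direction of the split did not hold. The most marked gene-named regions after GC correction and scaling were Samd12 (a difference of differences of 3.87), Nefm (−3.59), Impact (3.42), Nap1l5 (−3.19) and 1190002H23Rik (−3.15).

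In liver and spleen the regions that differed were mostly lower in aid-/-, on arrays with a lower plateau than those of mbd4-/-. A narrower range of log ratios on the aid-/- liver array may account for the liver part, since 54.1% of the regions that differ were lower once arrays were scaled to one plateau, against 90.1% before. In spleen the same scaling left 64.8% of the differing autosomal regions lower, against 96.8%. With X regions included, 132 were higher and 501 lower at one plateau, but 80 and 1243 at an equal spread and 40 and 536 in the deposited values. How far the range makes the spleen excess thus depends on the kind of scaling and stays open. The liver arrays shared 0 scan days, so scan day and genotype cannot be told apart in liver. A biological difference between the genotypes stays open and untested, since each tissue has 1 array per genotype and no wild type.

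Input DNA, which the comparisons use only as a denominator, was uneven between chromosomes on 4 arrays, which drew attention because a chromosome stood over 0.25 (log2) above the median array. In mbd4-/- spleen the input of chromosome X lay 0.646 above it. In ES cells the input was raised on chromosomes 1 (0.366), 8 (0.372) and 19 (0.376) in aid-/-, on 1 (0.299), 8 (0.336) and 11 (0.384) in wild type, and on 8 in the Gadd45a knockdown (0.368). On these chromosomes the median log ratio stood below that of the autosomes by −0.126 to −0.297, and on X in mbd4-/- spleen above it by 2.36. After GC correction and centring of each autosome the regions lower in ES aid-/- than in ES wild type numbered 245, against 328 with GC correction alone and 481 before.

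An added X chromosome, as in a female animal, may account for the X-linked regions that were higher in mbd4-/- spleen, since the X input was 0.626 higher than in aid-/- spleen. The labels do not give the sex of the animals. Loss of MBD4 as such would raise them in liver too, where the median X region differed by 0.200 between mbd4-/- and aid-/-, and slide or scan day would raise them in mbd4-/- liver, from the same slide and scan day, where the median was 0.323 against 2.28 in spleen. Xist, the RNA gene that silences 1 X chromosome in females, stood at 3.19 in mbd4-/- spleen and 4.38 in mbd4-/- liver. A biological effect of MBD4 in spleen alone stays open and untested.

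For ES cells against liver and spleen, 2 of the 35 splits of the 8 arrays into 4 and 4 gave as many regions in either direction, so chance is not excluded. The real split, in a fit of 2 groups, called 17 regions higher and 18 lower, and the highest other split called 283. That split set ES aid-/-, ES mbd4-/-, mbd4-/- liver and mbd4-/- spleen against the rest, which points to a structure of the samples. These are the 4 arrays with the highest plateaus (4.34, 4.31, 4.02 and 3.66, against at most 3.36), and whether the range of the arrays makes those calls was not tested. For aid-/- against mbd4-/- over 3 tissues, 10 of 10 splits gave as many regions, with a real value of 0 and a highest other value of 0. With 10 splits no share under 0.05 is possible.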

How the results depend on the processing

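The settings with GC correction, with arrays scaled to one plateau, with chromosomes centred, and with scan day or slide, and quantile normalisation for aid-/- against mbd4-/-, were chosen after seeing the data, and the other settings before the data were examined. For the regions named for the largest differences, members named from lists left aside, 1292 values under the alternatives kept their direction and their call. The call was lost in 110 values of comparisons of 2 arrays, by the rule of size, and in 156 values of limma contrasts. In 2 values the direction reversed. For gene lists 779 values counted as kept, 123 as moved, 24 as newly passing, 41 as no longer passing and 15 as reversed. In comparisons of 2 arrays, kept and moved go by the size of the shift in the list median alone. A change of sign was counted there only for lists near either end of the random lists. For camera, a list that passed in neither setting counts as kept even if its direction turned. The cause was not tested except where stated. Pairing by replicate number was not possible, because each group holds 1 array. Tissue and genotype, which the labels give, were used as blocks instead. Scan day as a random block could not be fitted for aid-/- against mbd4-/-. Bound signal stood above background at 65.5% of probes on the ES aid-/- array and at 81.1% to 92.3% on the others, so low values rest on fewer probes above background there.

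Regions higher in aid-/- than in wild-type ES cells (895) numbered 410 at an equal spread, 245 with normexp, 279 in the deposited values, 348 at one plateau, 278 with GC correction as well and 349 with at least 5 probes. Lower regions (481) numbered 255 centred on the low mode, 266 at an equal spread, 5 with normexp, 204 in the deposited values, 211 at one plateau, 177 with GC correction as well, 245 with GC correction and centred chromosomes, 249 with at least 5 probes and 313 without the probe filter. For mbd4-/- the higher regions (1044) became 360 at an equal spread, 160 with normexp, 417 in the deposited values, 384 at one plateau, 363 with GC correction as well and 428 with at least 5 probes, and the lower ones (316) became 134, 15, 158, 129, 117 and 151 in the same order. For the Gadd45a knockdown the higher regions (994) became 3194 centred on the low mode, 622 at an equal spread, 138 with normexp, 631 in the deposited values and 483 with at least 5 probes, and the lower ones (773) became 405 centred on the low mode and 329 with at least 5 probes. Regions lower in wild type than in all 3 other ES arrays (25) became 97 centred on the low mode, 2 with normexp, 43 in the deposited values, 15 with GC correction at one plateau and 7 with at least 5 probes.

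Differing regions in liver (1169) became 643 at an equal spread, 360 in the deposited values, 242 at one plateau, 262 with GC correction as well and 453 with at least 5 probes. In spleen (1101) they became 576 in the deposited values, 633 at one plateau, 705 with GC correction as well and 544 with at least 5 probes. At least 5 probes leaves fewer regions tested. Between liver and spleen (0) 30 passed at an equal spread and 7 in the deposited values. For aid-/- against mbd4-/- over 3 tissues (0), leaving out 1 array gave 0 to 1151. With tissue as a block, leaving out 1 array takes its whole tissue out of this contrast.

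Regions higher in ES cells than in liver and spleen (11) became 24 centred on the low mode, 49 at an equal spread, 0 with normexp, 88 with quantile normalisation, 34 in the deposited values, 69 at one plateau, 96 with GC correction as well, 2 with at least 5 probes, 17 on autosomes, 785 with genotype as a block on 6 arrays, 5 with scan day as a block, 162 within scan day 1, 26 with slide as a random block, and 0 to 123 with 1 array left out. Lower regions (18) became 100 centred on the low mode, 423 at an equal spread, 1 with normexp, 294 with quantile normalisation, 328 in the deposited values, 357 at one plateau, 401 with GC correction as well, 8 with at least 5 probes, 33 on autosomes, 746 with genotype as a block on 6 arrays, 0 with scan day as a block, 45 with slide as a random block, and 0 to 74 with 1 array left out. All 20 named regions of this contrast lost their call with normexp and without mbd4-/- liver, and 16 with scan day as a block. The calls lost were 19, 18 and 19 without ES aid-/-, ES wild type and ES mbd4-/-, and 0 without the Gadd45a knockdown.

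Hist1h2bk reversed to −0.104 in liver with normexp and to −0.108 in spleen with GC correction at one plateau. Among list medians near either end of the random lists, those that reversed were of pluripotency in aid-/- against wild type (−0.0395 with at least 5 probes), of Polycomb genes in mbd4-/- against wild type (0.0965 centred on the low mode, 0.0189 with GC correction and 0.0003 with centred chromosomes), of Polycomb genes in the Gadd45a knockdown (0.3572 centred on the low mode and 0.002 at an equal spread) and of germline genes in liver (0.3333 at one plateau and 0.3745 with GC correction as well). A reversal here is a change of sign of the list median, and centring on the low mode moved the median of all regions too. Other list medians changed sign as well, and part of them are given with their lists. For housekeeping genes in ES cells against tissues, the camera direction turned at an equal spread (median 0.015, camera adjusted p = 0.422), with quantile normalisation (0.084, 0.656), in the deposited values (−0.046, 0.859) and with GC correction at one plateau (−0.009, 0.693). For germline genes in aid-/- against mbd4-/- it turned with quantile normalisation (0.103, camera adjusted p = 0.0455), at one plateau (0.2, 0.0025) and with GC correction as well (0.289, 1.03e-05).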

Other observations

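The tests of explanations in this part, and the choice of the regions it names, were made after the results were seen.

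Some regions separated the ES arrays from one another and not by wild type against the rest. Nefm, a neurofilament gene, stood at 3.48 in ES mbd4-/- and 3.73 in the Gadd45a knockdown, at −0.34 in ES wild type and −0.69 in ES aid-/-, and at −0.75 to −0.03 in liver and spleen. The region 1190002H23Rik was high in the same arrays, at 4.10 in ES mbd4-/- and 2.67 in the knockdown, against 0.29 in ES wild type and −0.08 in ES aid-/-. B3galtl, a glycosyltransferase gene, stood at 2.33 and 1.00 in ES mbd4-/- and the knockdown, and at −0.30 and −1.06 in ES wild type and aid-/-. Samd12 showed the opposite order, at 3.50 in ES wild type and 4.23 in ES aid-/-, and at −1.12 and −0.43 in ES mbd4-/- and the knockdown, with −0.60 to −0.17 in liver and spleen. ES wild type and aid-/- were also scanned on day 1 and read with one version of the scanner software, and ES mbd4-/- and the knockdown on days 3 and 4 with another, so the order of these arrays cannot be told apart from the scan.

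Among imprinted genes, Impact stood at 4.12 in ES aid-/- and 0.53 in ES mbd4-/-, whereas Nap1l5 stood at 1.46 and 5.12 and Mcts2 at 1.57 and 4.56. ES wild type stood at −0.71, −0.26 and −1.04 at these genes. Mbd3, which encodes a methyl-CpG-binding domain protein, stood at 1.36 in ES wild type and −2.31 in the Gadd45a knockdown, and was higher than wild type in ES aid-/- by 1.74.

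The 18 imprinted regions that were higher in ES aid-/- and ES mbd4-/- than in ES wild type were weighed further. For these regions, a narrower range of log ratios on the wild-type array is argued against as the whole cause. After GC correction and scaling to one plateau, their median difference of aid-/- minus wild type was 2.98, with a lower quartile of 1.37. They were chosen for differing by at least 1 log2 before scaling, which favours that outcome. Over all 33 regions of the list, which were not chosen by these values, the medians in that setting fell under 1 log2. They were 0.81 for aid-/- and 0.91 for mbd4-/-, against 1.62 and 1.24 as measured, though above all random lists. The range may thus make part of the list's difference. An excess of X chromosomes in the wild-type line over the aid-/- line, as sampled, is argued against by an X input of −0.0569 for wild type minus aid-/-. That value cannot decide about the lines at an earlier time, or about a number of X chromosomes that both share. A candidate explanation that stays open is that ES lines differ in imprints apart from the targeted gene: the Gadd45a knockdown, at a median difference of 0.0294, was as low as wild type, but the labels do not name the lines and there is 1 wild-type array. An effect of the aid-/- and mbd4-/- genotypes stays open too, as a hypothesis.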
